A study of Xenopus tropicalis with 13 samples.

How the data were processed

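The series measured polyadenylated RNA from 13 single whole embryos, grouped by the labels as uninjected or MO-injected at stage 10 (3 and 3) or stage 15 (4 and 3). The labels do not say which of the morpholinos named in the series design was used, and no embryo labelled as injected with a mismatch morpholino or as a CRISPR mutant was among the 13. One uninjected embryo carries stage 15 in its title and stage field and stage 10 in its description, and was placed at stage 15. The stage 15 embryos are titled in 2 naming styles, and some title codes and letters are shared by injected and uninjected embryos. A batch or a common origin of such embryos is therefore possible, which cannot be modelled because the tables tie no value to an embryo. The submitters' processing notes name TopHat, Bowtie, Cufflinks, Cuffdiff, DESeq and DESeq2, with no versions, and no role for each. The aligner settings, annotation and genome build are not given in the sources used here.

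The authors' deposited expression tables hold, per the file headers, a mean normalised count, a log2 fold change with its standard error, a p-value and an adjusted p for each listed gene, in the layout of DESeq2. The mean normalised count, a size-factor scaled signal that the authors deposited, was identical at both stages for shared genes and so is taken over embryos of both stages. The headers of the expression tables name no direction. It was set from the data: across genes with a listed bin, the log2 ratio of raw bin counts (MO-injected over uninjected) correlated with the deposited log2 fold change, with a Spearman correlation of 0.709 at stage 10 over 11 genes and 0.692 at stage 15 over 169 genes. Positive values are therefore read as higher in MO-injected embryos. The 944 higher genes at stage 15 were also deposited as a table of their own, with the same folds.

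The authors' deposited bin tables hold, per the file headers, raw counts per embryo of each listed bin, their mean (signal), fitted usage scores of both conditions, a log2 ratio of usage, a p-value and an adjusted p. The deposited ratio is uninjected over MO-injected and its sign was turned. The scale of the usage scores is not given in the sources used here, and their ratio differs from that of the raw counts in both directions. The count columns carry a number that the labels do not tie to an embryo, and those of the stage 15 table are named for stage 10 while its fitted columns are named for stage 15. They were used as stage 15, since there are 4 uninjected columns and the counts differ from those of the other table. The repeated header at the end of each bin table was left out, and 1 row whose name and gene field disagree, apart from names turned into dates, was used by its gene field. A retention score of 1 or 2 that the authors deposited on some stage 15 bins has no stated meaning and was not used, and the authors' deposited numbers of retained introns were copied as they stand. No column of per-embryo values was left unused.

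The tables list items past an adjusted p of 0.1. From the Benjamini-Hochberg relation between p and adjusted p, at least about 13348 genes were tested at stage 10. At least about 293 reach this level, against 292 listed, so this lower bound shows no removal beyond rounding and cannot exclude one. At stage 15 at least about 15916 genes were tested and at least about 4366 reach the level. At least about 2272 were therefore removed before deposit, from a list that holds no gene under 2-fold. For bins, at least about 162381 and 192075 were tested, and at least about 1319 and 6629 reach the level, against 228 and 1429 listed. Because the lists are selected, no model was refitted and the adjusted p-values are those of the authors. Of the 292 and 2094 gene identifiers, 249 and 1388 matched a symbol or synonym in RefSeq's table for the assembly UCB_Xtro_10.0, which was used for nothing else. Identifiers turned into dates by spreadsheet software (1 and 7) and those of the form Xetro (36 and 619) were kept in counts and not named by the rule.

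Counts of listed genes and bins by direction were compared with Fisher's exact test and exact binomial tests, all two-sided, in scipy 1.17.1, with odds ratios pooled over strata from statsmodels 0.14.6. The difference of log2 fold changes between stages was tested with a Wald test on the deposited standard errors, with Benjamini-Hochberg adjustment over the 53 shared genes. This test was run on simulated data of 2000 genes with the deposited standard errors. It called 73% of genes with a true log2 difference of 2 and 91% of those with a difference of 3, and 5.20% of its calls had no difference. The simulated genes were not selected, whereas the 53 shared genes were selected at both stages, so these shares need not hold for them. Ratios of mean raw counts used a pseudocount of 0.5, and since the depth of each embryo's library is unknown they are not corrected for it, and no interval that needs the depth is given. Totals over listed bins ranged from 1105 to 1440 reads in uninjected and from 12088 to 17650 in MO-injected embryos at stage 10, and from 4922 to 8389 and 50451 to 83767 at stage 15. These are totals of selected bins and not library depths.

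Before the data were examined, 22 gene lists and their test, the tests of direction between and within the stages and the rule for named genes were fixed. The planned tests of bin direction had no content, because no listed bin was lower. The comparison of genes with a bin against other listed genes, the Wald test between stages, the overlaps of independent lists, the comparison of lowest and highest raw counts and the strata of mean count were chosen after the tables had been seen. The rule took taf15, the listed members of each list (at most 4 in full, those of largest change), the 5 largest and 5 smallest changes and the 5 smallest adjusted p-values with a gene symbol, 1 bin per gene, the 8 persistent genes of smallest adjusted p at stage 10, and fgfr4, isl1, pax8 and ventx2.1 whatever their values. Some genes are not reported here and were left out of the gene groups put together after the data were seen. Genes listed at both stages, genes with both a bin and a change in level, list members beyond 4 and bins given for their read counts were named after their values were seen. Alternatives fixed beforehand were a 4-fold threshold, an adjusted p of 0.01, rows with a symbol only, leaving out the genes or bins of lowest mean count, other ways of matching, and 1 bin per gene. Reads shared by overlapping or antisense genes cannot be set apart, as the counting is not described in the sources used here.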

Results

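RNA was sequenced from single whole embryos of the western clawed frog, Xenopus tropicalis, either uninjected or injected with an antisense morpholino oligonucleotide (MO) against Taf15, an RNA-binding protein. Embryos were collected at stage 10, the start of gastrulation, and at stage 15, when the neural plate folds. There were 3 uninjected and 3 MO-injected embryos at stage 10, and 4 uninjected and 3 MO-injected embryos at stage 15. The deposited tables held genes whose expression differed between MO-injected and uninjected embryos and gene segments (bins) whose share of their gene's reads differed. Both kinds of table listed only items past the authors' threshold, so a gene that is absent from a list was not shown to be unchanged. The total count of each library was not in the tables used here and its depth is unknown. All embryos are separate animals. The authors' adjusted p-values rest on the spread between these embryos, and the tests of lists count genes.

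The first question was which transcripts changed in level at the start of gastrulation. At stage 10, the authors' deposited table listed 292 genes, of which 127 were higher and 165 were lower in MO-injected embryos. Of these, 157 changed by less than 2-fold. The targeted gene taf15 was in none of the lists at either stage, so the tables hold no check of the knockdown at the level of RNA. Of genes with a symbol, the smallest adjusted p in the authors' deposited table was that of rpn2, a subunit of the oligosaccharyltransferase complex, with a log2 fold change of -3.70 (SE 0.164, adjusted p = 3.49e-108). It was followed in the authors' deposited table by prc1.2, a homologue of a cytokinesis regulator, at 2.16 (SE 0.206, adjusted p = 6.00e-22), and by alpl, an alkaline phosphatase, at -3.0 (SE 0.322, adjusted p = 4.99e-17). The gene arhgap11a.2 rose by 2.08 (SE 0.252, adjusted p = 4.21e-13) and lonrf3 by 4.07 (SE 0.504, adjusted p = 1.83e-12) on the log2 scale in the authors' deposited table. Among genes with a symbol, the largest increases in the authors' deposited table were those of cyb561 (log2 fold change 4.38, SE 0.852), lonrf3, the metalloprotease gene adam19 (3.84, SE 1.11), chad (2.98, SE 0.806) and rasl11a (2.55, SE 0.800). Besides rpn2 and alpl, the largest decreases of genes with a symbol in the authors' deposited table were those of the calcium/calmodulin-dependent kinase gene camk4 (-3.69, SE 1.00), ninj1 (-2.95, SE 0.879) and foxi1 (-2.74, SE 0.561), a transcription factor of epidermal ionocytes.

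Of the gene lists fixed beforehand, only that of neural progenitors and neurons had enough members for a test at stage 10. All 5 of its listed members fell, which did not pass the exact binomial test against the 43.5% of higher genes in the whole table (p = 0.0732). In the authors' deposited table they were the neurogenic zinc-finger gene myt1 (log2 fold change -1.98, SE 0.503), the Delta ligand gene dlc (-1.59, SE 0.410), insm1 (-1.02, SE 0.329), the neuronal RNA-binding protein gene elavl3 (-1.0, SE 0.279) and sox21 (-0.82, SE 0.216). The neural crest list had 3 listed members, all higher in the authors' deposited table: adam19, snai1 (log2 fold change 1.18, SE 0.156) and snai2 (1.14, SE 0.328), the last 2 being repressors of the Snail family. The epidermal list had foxi1 and tp63, a regulator of basal epidermis (-1.01, SE 0.327), both lower in the authors' deposited table. Of the cement and hatching gland markers, agr2 was higher (2.07, SE 0.459) and dlx3, which also stands on the placode list, was lower (-1.98, SE 0.451) in the authors' deposited table. Among signalling genes in the authors' deposited table, the receptor gene fgfr4 was higher (0.85, SE 0.225, adjusted p = 0.0162), as were the immediate early gene fos (1.30, SE 0.251), the Nodal-pathway factor foxh1 (0.89, SE 0.193), gata2 (0.60, SE 0.175) and the Wnt co-receptor gene lrp5 (0.47, SE 0.151), whereas wnt8a was lower (-0.91, SE 0.292). Other listed members in the authors' deposited table were hoxb6 (2.06, SE 0.618), mespa of the somite list (1.09, SE 0.237) and the maternal gene btg4 (1.80, SE 0.482), which were higher. The forebrain gene nr2e1 (-1.79, SE 0.515) and the splicing genes smn2 (-1.08, SE 0.214) and hnrnpk (-0.55, SE 0.158) were lower in the authors' deposited table. The remaining lists had no listed member at stage 10, among them those of endoderm, notochord, kidney and heart, p53, interferon, heat shock and chromatin genes. None of isl1, pax8 and ventx2.1 was listed for expression at stage 10.

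At stage 15 the question was the same for the neurula. The authors' deposited table listed 2094 genes, 944 higher and 1150 lower in MO-injected embryos, all of them at least 2-fold. The largest decrease of a gene with a symbol in the authors' deposited table was that of myh4, a skeletal muscle myosin heavy chain, with a log2 fold change of -7.96 (SE 0.379, adjusted p = 1.12e-93). The hindbrain segment gene egr2 fell by 5.27 (SE 0.301, adjusted p = 1.18e-64), zfand3 by 3.24 (SE 0.186, adjusted p = 1.84e-64) and nvl by 3.96 (SE 0.234, adjusted p = 6.93e-61) on the log2 scale in the authors' deposited table. The pigment cell glycoprotein gene gpnmb completed the 5 smallest adjusted p-values of genes with a symbol in the authors' deposited table with a rise of 2.95 (SE 0.235, adjusted p = 6.69e-33). Among genes with a symbol, large decreases in the authors' deposited table also included tshz2 (-6.52, SE 1.58), the ciliary gene spag17 (-6.17, SE 0.648), clec2d (-6.16, SE 1.62) and the receptor tyrosine kinase gene alk (-6.10, SE 1.33). Among genes with a symbol, the largest increases in the authors' deposited table were those of slc22a13 (8.26, SE 0.977), the sugar transporter gene slc2a7 (6.92, SE 1.41), cfhr2 (6.43, SE 0.839), btg4 (6.39, SE 0.777) and kbtbd13 (5.98, SE 1.05). Some of these rest on few reads, since the mean normalised count over all embryos in the authors' deposited table was 4.00 for clec2d, 4.59 for tshz2 and 6.31 for slc2a7.

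Of the 22 gene lists fixed beforehand, 13 had 5 or more listed members at stage 15. Their direction was compared with the 45.1% of higher genes in the whole table by exact binomial tests, two-sided, with Benjamini-Hochberg adjustment over the 13 lists. These tests treat genes as independent, which they are not, and ask about direction among listed genes rather than enrichment. A count adjusted over the list alone could not be formed, because the tables hold no p-values of unlisted members.

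All 10 listed members of the maternal and germ plasm list were higher (adjusted p = 0.00451). They included btg4, an adaptor of messenger RNA deadenylation in the egg, the egg coat gene zp3 with a log2 fold change of 2.97 (SE 0.303), the oocyte growth factor gene gdf9 at 2.40 (SE 0.442) and zar1l at 2.26 (SE 0.342) in the authors' deposited table. All 8 listed members of the Nodal and organizer list were higher (adjusted p = 0.00739), among them sia2 (3.17, SE 0.784), nodal (2.72, SE 0.633), the mesendoderm factor mixer (2.14, SE 0.345) and foxh1.2 (1.86, SE 0.714) in the authors' deposited table. The endoderm and maternal determinant vegt was higher by 1.77 (SE 0.155, adjusted p = 7.44e-27) in the authors' deposited table. It was the only listed gene of the endoderm list.

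Of the BMP and dorsoventral list, 10 of 11 listed members were higher (adjusted p = 0.0118). They were led in the authors' deposited table by ventx3.1 (2.23, SE 0.310) and ventx3.2 (2.07, SE 0.231), homeobox genes of the ventral side, and by admp (1.82, SE 0.242), a dorsally expressed BMP-like ligand. The related gene ventx2.1 was at 1.52 (SE 0.245, adjusted p = 3.34e-08) in the authors' deposited table, while of the BMP antagonist genes chrd was higher (1.05, SE 0.225) and nog2 was the member of the list that fell (-1.99, SE 0.464). The 5 listed members of the FGF and ERK list were all higher (adjusted p = 0.0484), and in the authors' deposited table were spred3 (1.97, SE 0.327), fgfr4 (1.86, SE 0.211), fos (1.80, SE 0.263), cdx1 (1.13, SE 0.222) and the mesodermal T-box gene t (1.05, SE 0.154). The counting of reads is not described, so the rise of fgfr4 may include reads of its listed bin, described below. Without fgfr4 the list would have too few members for the test. The Wnt list had 2 of 7 listed members higher (adjusted p = 0.610), with tcf7l2 (-3.80, SE 0.418), dvl1 (-2.97, SE 0.780) and wnt11 (-1.84, SE 0.362) lower and the antagonist gene frzb (1.67, SE 0.318) higher in the authors' deposited table.

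Genes of differentiating muscle went the other way. In the muscle and somite list 15 of 16 listed members fell and 1 rose (adjusted p = 0.00739). After myh4 the largest decreases of the list in the authors' deposited table were those of the fast troponin gene tnnc2 (-3.85, SE 0.526), acta2 (-3.02, SE 0.739) and the sclerotome gene pax1 (-2.62, SE 0.601), and the member that rose was the actin gene acta1 (1.73, SE 0.269). In the anterior neural and eye list 9 of 10 listed members fell, which did not pass the test (adjusted p = 0.0512). The homeobox genes vax1 (-4.55, SE 1.29), lhx9 (-3.67, SE 0.606), six6 (-3.36, SE 0.561) and vax2 (-2.45, SE 0.311) were lower in the authors' deposited table, and lhx5 was higher (1.57, SE 0.195). Of 8 listed genes of the p53 and DNA damage list, 7 were higher (adjusted p = 0.0512), among them eda2r (3.91, SE 0.979), ccng1 (3.03, SE 0.918), fosl1 (2.25, SE 0.798) and tp53inp1 (1.96, SE 0.357), while fas was lower (-1.56, SE 0.498) in the authors' deposited table. Few reads underlie vax1 and fosl1, whose mean normalised counts over all embryos were 4.24 and 8.27 in the authors' deposited table.

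The other lists did not pass the test or were too short for one. The midbrain, hindbrain and spinal cord list had 2 of 6 listed members higher (adjusted p = 0.798); besides egr2, en2 fell by 2.42 (SE 0.335) and the retinoic acid hydroxylase gene cyp26c1 by 2.14 (SE 0.268), and hoxd4 rose by 1.25 (SE 0.223), in the authors' deposited table. Neural progenitor and neuron genes went both ways, with 3 of 8 higher (adjusted p = 0.798), including isl1 at 1.25 (SE 0.276, adjusted p = 0.000107), neurod2 at 3.40 (SE 1.15) and olig3 at 2.03 (SE 0.333), and dbx1 at -1.95 (SE 0.345) and sox1 at -1.67 (SE 0.447) in the authors' deposited table. In the neural crest list 5 of 6 listed members fell (adjusted p = 0.377), led by sox10 (-3.77, SE 0.445), tfap2b (-2.13, SE 0.291), pax7 (-1.96, SE 0.648) and tfap2e (-1.17, SE 0.373), whereas snai1 was higher (1.06, SE 0.145) in the authors' deposited table. Of the notochord and floor plate list 3 of 6 were higher (adjusted p = 1.0), and of the multiciliated cell and epidermis list 1 of 5 (adjusted p = 0.559). With fewer than 5 listed members, and so untested, all 4 of the kidney, heart, blood and vessel list were lower in the authors' deposited table, including the cardiac factor genes nkx2-5 (-1.42, SE 0.230) and hand2 (-1.40, SE 0.467). Of the interferon list 3 of 4 were higher in the authors' deposited table, including ifit5 (4.16, SE 0.714) and the RNA sensor gene ddx58 (2.19, SE 0.847). Few reads underlie ddx58 and neurod2, whose mean normalised counts over all embryos were 5.48 and 5.595 in the authors' deposited table. Single or few members of the other lists in the authors' deposited table were crx (1.5, SE 0.206) and atoh1 (-1.49, SE 0.452) for placodes, hmox1 (-1.46, SE 0.374) for stress, dnmt1 (-1.04, SE 0.167) for chromatin, and hnrnph1 (1.03, SE 0.151), smn2 (-1.44, SE 0.209) and mbnl2 (-1.20, SE 0.311) for splicing. No symbol of the cement and hatching gland list was listed for expression at stage 15, nor was pax8. Lists were matched by symbol and not by synonym, so a member under another name would be missed.

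**Figure D1:**
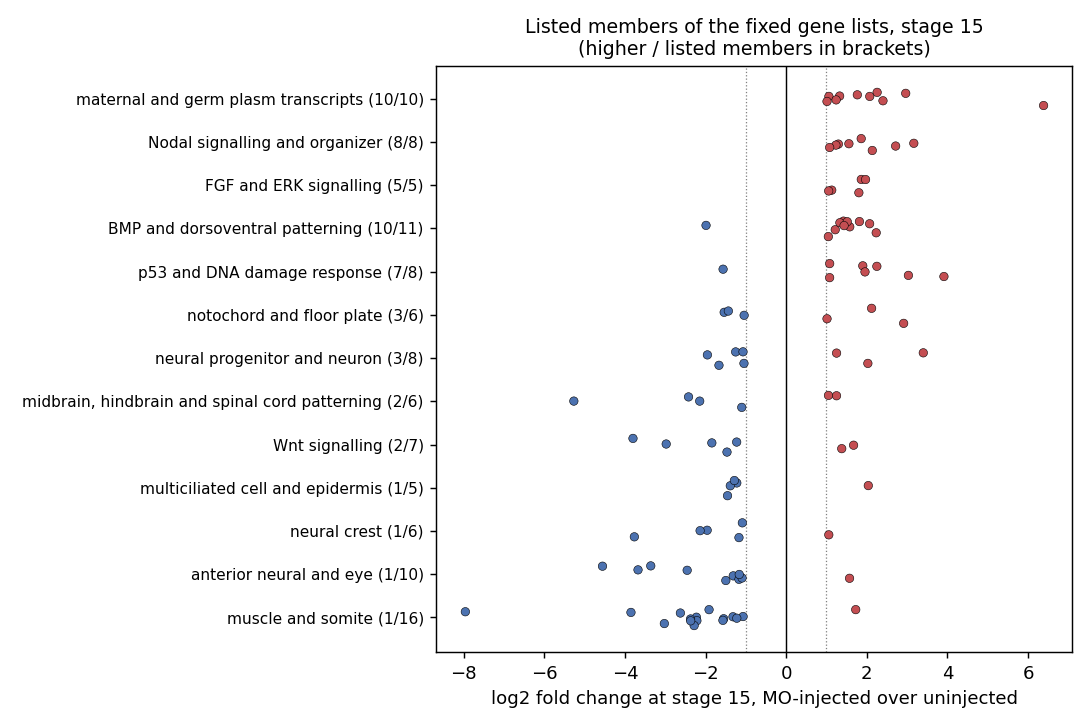
Log2 fold change at stage 15 (MO-injected over uninjected, horizontal axis) of every listed member of the 13 fixed gene lists with 5 or more listed members; each point is a gene, red if higher and blue if lower, and dotted lines mark 2-fold. All 10 maternal and germ plasm genes lie on the right, and 15 of 16 muscle and somite genes on the left.

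The balance of higher and lower genes was then compared between the stages. No difference was found between the lists as deposited, with an odds ratio of 0.938 (Fisher's exact test, two-sided, p = 0.616). Only the stage 15 list is limited to changes of 2-fold or more. With that limit on both lists the odds ratio was 0.812 (Fisher's exact test, two-sided, p = 0.284). The 2 lists shared 53 genes, of which 46 moved in the same direction (exact binomial test against 0.5, p = 4.00e-08). There were 26 genes higher and 20 lower at both stages. Independent lists drawn from the at least about 13348 tested genes that the deposited p-values imply would share 8.98 and 14.2 or fewer. Genes that rose at both stages in the authors' deposited tables included lonrf3 (4.07 then 2.75), chad (2.98 then 3.03), rasl11a (2.55 then 2.63), arhgap11a.2 (2.08 then 2.14), btg4 and snai1. Genes that fell at both stages in the authors' deposited tables included alpl (-3.0 then -1.78), rbm23 (-1.23 then -3.0), slc27a2 (-1.85 then -2.30) and smn2. For 20 of the 53, the difference between stages passed a Wald test built from the deposited standard errors (Benjamini-Hochberg adjusted p under 0.05). The rise of fgfr4, which may include reads of its listed bin, was larger at stage 15 than at stage 10, by 1.02 (SE 0.309, adjusted p = 0.00407) on the log2 scale from the authors' deposited tables. A total of 7 genes changed direction. Those higher at stage 10 and lower at stage 15 in the authors' deposited tables were jph1 (1.31 then -1.12), which encodes a protein of muscle membrane junctions, dmrta2 (1.48 then -1.50), znf385b (1.46 then -1.39) and timp3 (0.84 then -1.06). Lower at stage 10 and higher at stage 15 in the authors' deposited tables were has-rs (-1.71 then 1.88), zc3h6 (-0.96 then 1.02) and a gene known by the identifier Xetro.D01070 (-1.64 then 1.68).

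**Figure D2:**
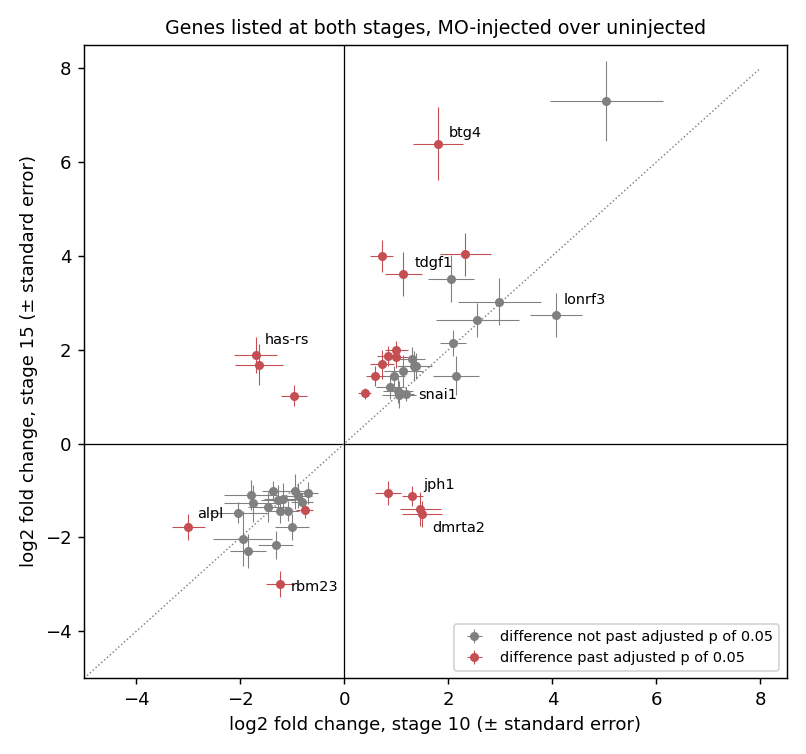
Log2 fold change (MO-injected over uninjected) at stage 10 (horizontal axis) and stage 15 (vertical axis) of the 53 genes listed at both stages; bars are the authors' standard errors, red points passed the test of the difference between stages and the dotted line marks equal change. Of the 53 genes, 46 lie in the quadrants of equal direction, and jph1 and dmrta2 are among the 7 that do not.

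The next question was which parts of transcripts changed in use. Bins are pieces of a gene, and a bin's usage is its level relative to the rest of its gene. At stage 10 the authors' deposited table listed 228 bins in 192 genes, and at stage 15 it listed 1429 bins in 1046 genes. Every listed bin was higher in MO-injected embryos, with a median log2 usage change of 1.62 at stage 10 and 1.75 at stage 15 in the authors' deposited tables. None was below 2-fold and none was lower, so tests of direction had no content. In raw counts, the lowest MO-injected embryo exceeded the highest uninjected embryo in 222 of the 228 bins at stage 10 and in 1079 of the 1429 at stage 15, where chance gives 5% and 2.86% for unselected bins. These bins were selected as higher from the same counts, so this is a description and not a test. No uninjected embryo had a read in 49 of the bins at stage 10 and 229 at stage 15. Most bins were thinly covered: the mean raw count over embryos was under 10 in 134 bins at stage 10 and in 854 at stage 15.

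Of genes with a symbol, fgfr4 had the smallest adjusted p at stage 10. Its bin E003 spans bases 74879002 to 74881098 of scaffold 3 (2097 bases; genome build not given in the sources used here), and the authors placed it in the 1st intron. The raw count of this bin was 5726 ± 1097 (SD, n = 3) in MO-injected and 205 ± 56.9 (SD, n = 3) in uninjected embryos at stage 10. At stage 15 it was 6663 ± 2093 (SD, n = 3) against 74.5 ± 15.4 (SD, n = 4). The usage change in the authors' deposited tables was 1.64 (adjusted p = 3.41e-172) at stage 10 and 1.56 (adjusted p = 8.62e-151) at stage 15. A bin of isl1, a LIM homeobox gene of motor neurons and heart, lay at bases 22743817 to 22745964 of scaffold 1. It had 34.0 ± 23.6 (SD, n = 3) reads against 3.67 ± 4.73 (SD, n = 3) at stage 10 and 2015 ± 75.0 (SD, n = 3) against 57.2 ± 25.8 (SD, n = 4) at stage 15. The authors' deposited tables gave usage changes of 1.64 (adjusted p = 1.01e-06) and 1.62 (adjusted p = 2.89e-23) for it. For pax8, a paired-box gene of the kidney and ear, a bin was listed only at stage 15, at bases 11850401 to 11850874 of scaffold 3, with 252, 177 and 165 reads in MO-injected and 4, 0, 0 and 4 in uninjected embryos. Its usage change in the authors' deposited table was 3.2 (adjusted p = 4.28e-154). Neither ventx2.1 nor taf15 had a listed bin.

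**Figure D3:**
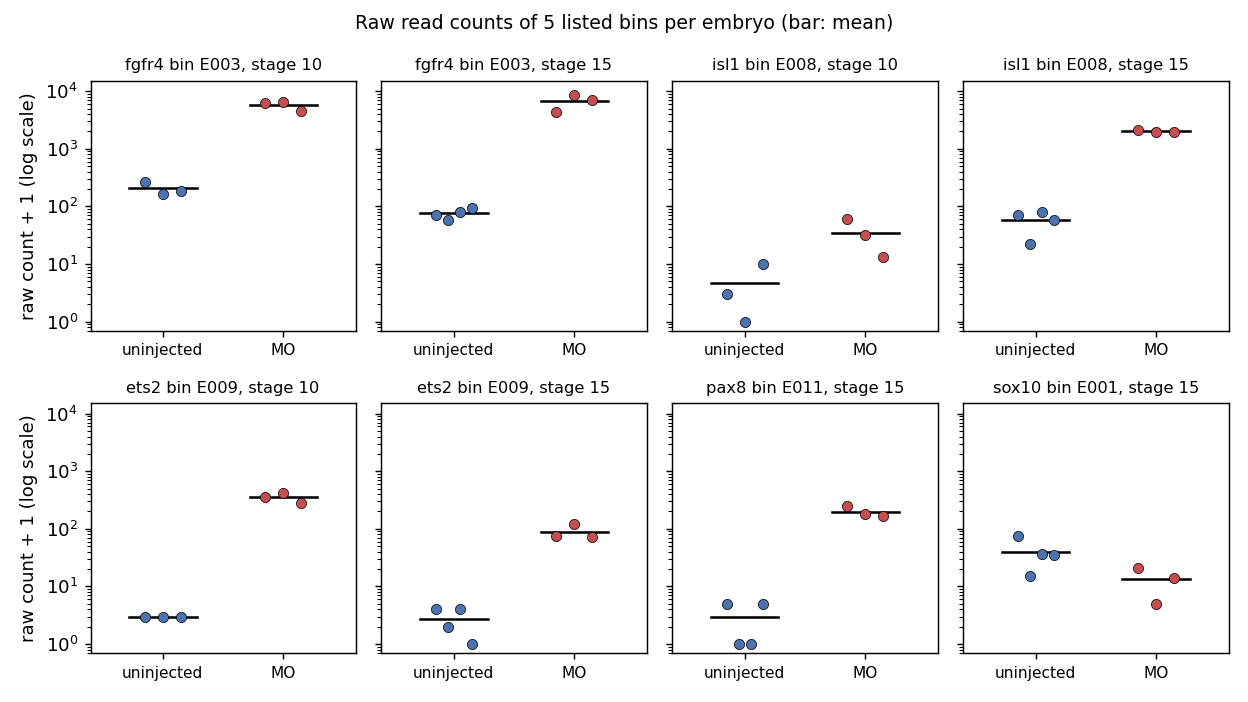
Raw read count plus 1 (vertical axis, log scale) of listed bins in fgfr4, isl1, ets2, pax8 and sox10; each point is an embryo, blue uninjected and red MO-injected, and bars are means. In the fgfr4, isl1, ets2 and pax8 panels every MO-injected embryo lies above every uninjected embryo, and in the sox10 panel the mean is lower in MO-injected embryos.

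Other genes with a symbol and the smallest adjusted p at stage 10 were the ETS factor ets2, the transcription factor tfap4, the muscle glycogen phosphorylase pygm and the translation initiation factor eif2s2. Their log2 usage changes in the authors' deposited table were 3.34, 2.1, 1.5 and 1.63. The ets2 bin had 350 ± 71.2 (SD, n = 3) reads in MO-injected embryos against 2, 2 and 2 in uninjected embryos. At stage 15 the phosphatase gene ctdsp2 had the smallest adjusted p (3.18e-241) of genes with a symbol in the authors' deposited table, with 22 listed bins. In its leading bin, 296 ± 37.7 (SD, n = 3) reads stood against 6.25 ± 3.50 (SD, n = 4). The next genes with a symbol in the authors' deposited table were pax8, fgfr4, the complement pathway protease gene masp1 with a usage change of 2.89 and the complement component gene c5 with 3.75. With the bin of smallest adjusted p taken for each gene with a symbol, the largest usage changes belonged to bins with no read in any uninjected embryo, most of them with few reads in MO-injected embryos. At stage 10 these were bins of adhfe1 (6, 2 and 1 reads in MO-injected embryos), pdcd7, ctdsp2, pggt1b and ephx1, and at stage 15 of bcas3, nkain1, ryr1, farp2 and eml5 (5, 8 and 7 reads). Of the same bins, the smallest changes in the authors' deposited tables were 1.00 to 1.03 for bins of dus4l, c16orf72, gcfc1, lrrc14 and pip5k1a at stage 10. They were about 1.00 for bins of ect2, myadm, ndst2, slc2a12 and haus6 at stage 15 in the authors' deposited table.

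Bins of developmental genes were spread over many lists. At stage 15 the FGF and ERK list had bins in 6 genes, RNA splicing in 5, and neural progenitor, neural crest, muscle and p53 lists in 4 each. In the FGF and ERK list, hras had 97.7 ± 36.1 (SD, n = 3) reads in MO-injected embryos and none in the 4 uninjected embryos, in a bin of 6 bases. In the neural crest list, ets1 had 154 ± 14.7 (SD, n = 3) against 6.50 ± 2.65 (SD, n = 4). The p53 list was led in reads by rrm2b, a ribonucleotide reductase subunit gene, with 751 ± 217 (SD, n = 3) against 21.0 ± 13.1 (SD, n = 4), and by plk3 with 566 ± 169 (SD, n = 3) against 39.5 ± 9.75 (SD, n = 4). Among splicing genes, srsf4 had 248 ± 83.7 (SD, n = 3) against 25.8 ± 12 (SD, n = 4), and hnrnpm had 98.0 ± 21.0 (SD, n = 3) against 9.75 ± 4.99 (SD, n = 4). Other bins at stage 15 were those of bmper, bmpr1b and bmp7.1 in the BMP list, znrf3, dvl3 and wnt3a in the Wnt list, jag1 and myt1 in the neural list, meis1 in the anterior neural list, irx2 in the hindbrain list and taf7 in the chromatin list. At stage 10 the lists had bins in fgfr4 and hras, bmp7.1 and id3, sfrp2, gsk3b and znrf3, irx2, jag1, runx1 and isl1, ets1, eda2r, and prpf6 and srsf4. The authors' deposited summary of retained introns counted a single intron in 6 of the 10 genes it lists at stage 10 and in 7 of 10 at stage 15, and in all 10 genes at each stage its number equalled the number of listed bins of the gene.

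Some bins were listed at both stages. There were 108 such bins, 47.4% of those at stage 10, and they lay in 81 genes, where independent lists drawn from the tested bins would share 2.01. Their coordinates were identical in the stage tables, and their usage changes correlated across bins (Spearman correlation 0.459; bins are not independent). In all, 90 genes had a listed bin at both stages. The persistent genes of smallest adjusted p at stage 10 were fgfr4, ets2, tfap4, pygm, eif2s2, irx2, dgka and asxl1. In tfap4, 193 ± 29.7 (SD, n = 3) reads against 5.33 ± 1.15 (SD, n = 3) at stage 10 were followed by 294 ± 26.5 (SD, n = 3) against 7.25 ± 6.60 (SD, n = 4) at stage 15, and the ets2 bin had 88.3 ± 28.4 (SD, n = 3) against 1.75 ± 1.5 (SD, n = 4) at stage 15. For dgka the leading bins of the stages differed. The authors' deposited table of persistent genes held 100 genes, of which all 100 had a listed bin at stage 15 and 75 had one at stage 10. A group of 8 named genes with bins at both stages was absent from it, among them adar, eda2r and smurf2.

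The last comparison asked whether genes with a changed bin also changed in level. At stage 10, 11 genes were in both lists, 5 higher and 6 lower, a share of higher genes of 45.5% against 43.4% among the other listed genes (odds ratio 1.09, Fisher's exact test, two-sided, p = 1.0). They included fgfr4, cdc6 and tfap4 among the higher and alpl, prmt3, aldoa, atpaf2 and ctdsp2 among the lower genes. At stage 15, 169 genes were in both lists, 51 higher and 118 lower. The share of higher genes was 30.2% among these and 46.4% among the other 1925 listed genes (odds ratio 0.50, Fisher's exact test, two-sided, p = 4.97e-05, genes treated as independent). Both lists come from the same embryos, and this comparison with the other listed genes was chosen after every listed bin had turned out higher, which left the planned test of bin direction against gene direction without content. Whether the reads of a bin count towards the level of its gene is not described. The rises in level of fgfr4 at both stages and of isl1 at stage 15 may therefore include reads of their bins. Where a gene fell, the raw count of its leading bin was still higher in MO-injected embryos in the median of the 118 genes (log2 ratio 1.45, not corrected for depth). An exception was the neural crest gene sox10, whose listed bin had 12.3 ± 8.02 (SD, n = 3) reads in MO-injected and 39.2 ± 25.1 (SD, n = 4) in uninjected embryos while its usage change in the authors' deposited table was 1.14 (adjusted p = 0.000329).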

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

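The tests of low mean counts and of mean counts among genes with a bin were written down before their results were seen, and the other tests of explanations were chosen after the patterns were seen. No model was fitted across genes here, so no count of other splits of the embryos was made.

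A total of 20 genes differed between the stages in their response by a Wald test of the difference itself. The log2 fold change at stage 15 minus that at stage 10, from the authors' deposited tables, was 4.58 for btg4, 3.59 for has-rs, 3.32 for Xetro.D01070, 3.27 for Xetro.I00996, 2.48 for tdgf1, a co-receptor of Nodal signalling, 1.99 for zc3h6 and 1.71 for Xetro.E01322. It was 1.22 for alpl, 1.02 for fgfr4, 0.98 for got2, 0.96 for mov10l1, 0.85 for gpi, 0.85 for gpbp1 and 0.67 for smcr7l in the authors' deposited tables. It was negative for dmrta2 (-2.99), znf385b (-2.86), jph1 (-2.43), timp3 (-1.89), rbm23 (-1.77) and aldoa (-0.66) in the authors' deposited tables. The genes were selected at both stages, and that at stage 15 only changes of 2-fold or more were deposited favours larger differences.

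In 6 of 47 named bins at stage 15, 1 of the 4 uninjected embryos stood apart from the others. The chance value of about 2.35 holds for continuous values and does not apply to counts of 0 and 1, where a single differing embryo always stands apart. The gap to the nearest embryo divided by the range was 0.842 for the bin of asxl1, where 26 reads stood above 7, 7 and 10. It was 0.875 for bmper, where 4 reads stood below 11, 12 and 12. It was 1.0 for the bins of etv4, sos1, pax3 and wnt3a, in which no uninjected embryo had more than 1 read, so these 4 say nothing about an embryo.

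At stage 15, lists of maternal and early embryonic genes were mostly higher and muscle genes mostly lower in MO-injected embryos. Noise in genes of few reads over both stages is argued against. With genes under the median mean count left out, 80% of the 5 lists past the threshold stayed past it in the same direction. The FGF and ERK list had too few members left. That mean count covers embryos of both stages, so a gene with few reads at stage 15 alone could be kept. Noise in such genes is not excluded. A general response to injection may contribute, since 87.5% of the listed p53 genes were higher, and no embryo injected with a control morpholino was analysed here. Slower development of the injected embryos may also contribute: germline and sarcomere gene groups moved as it predicts (exact binomial tests, largest adjusted p = 0.0223), but they were put together after the values were seen. Of the other groups, synaptic genes were mostly lower (24 of 29), as it predicts. Photoreceptor genes, many of them with few reads, were mostly higher (11 of 12), which it does not predict if they stand for late differentiation. Stage 15 is well before photoreceptors form, so its prediction for them is unclear. Pigment genes were mostly higher (5 of 6), which slower development does not predict if they too stand for late differentiation. That did not pass the exact binomial test against the whole table (adjusted p = 0.0972), but passed against genes with a symbol (adjusted p = 0.0400). Slower development cannot be told apart from an effect of Taf15 on these genes, because no uninjected embryos of intermediate age were analysed here, and that effect stays open as untested.

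At stage 15, genes with a higher bin were more often lower in level than other listed genes, a comparison chosen after the tables had been seen. A difference between these sets in mean count over both stages is argued against as the whole cause. The odds ratio pooled within 4 strata of that mean count was 0.491 (Mantel-Haenszel p = 3.89e-05 over 2094 genes, not an exact test), close to the unstratified value. The strata were not all alike. In the lowest, 4 genes with a bin were higher and 3 lower, against 262 and 255 of the others. In the highest, the counts were 23 and 52 against 249 and 200, and the strata between went the same way. Whether the strata differ was not tested. Mean counts at stage 15 alone were not held in the tables used here. Unchanged intron reads beside falling messenger RNA may raise the usage of a bin. Over the genes that fell, the median log2 ratio of raw bin counts was 1.45, and this cannot be told apart from a difference in library depth, which the tables do not hold. An effect of retained introns on transcript level stays open as untested.

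Every listed bin was higher in MO-injected embryos. Removal of rows before deposit may account for part of this: the p-values imply at least 6629 bins at the adjusted p of the last stage 15 bin, against 1429 deposited, and the direction of the others is not known. Genomic DNA carried over into the MO-injected libraries would add reads evenly along the genome, and is argued against as the whole cause. In stage 15 bins of 500 bases or more, the 90th percentile of extra reads per base was 29.7 times the 10th, with 137 against 4.62 extra reads per kilobase and 3142 in the fgfr4 bin. A loss of intron removal on depletion of Taf15, and transcripts that start or end within these bins, stay open as untested.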

How the results depend on the processing

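No paired analysis was possible because the count columns carry a number that the labels do not tie to an embryo's letter, and the expression tables hold no values per embryo. For the same reason replicates could not be left out of the expression results, and no pseudocount applied to them. The 2-fold threshold for both lists, the median mean count, the strata of mean count, the list tests among genes with a symbol and the raw 2-fold counts were chosen after seeing the data. Of 68 alternative values of the main results 52 stayed close to the value as deposited, 15 counts moved by more than 1.5 times and 1 ratio changed side. The 5 gene lists past the threshold stayed past it in the same direction in all 21 settings with 5 or more listed members.

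Stricter thresholds moved the counts by construction. At 4-fold or more there were 15 higher and 10 lower genes at stage 10 and 344 and 372 at stage 15. At an adjusted p under 0.01 there were 44 higher and 59 lower genes at stage 10 and 583 higher and 772 lower genes at stage 15. At 2-fold or more, 54 were higher and 81 lower at stage 10, and with gene symbols only, 581 were higher and 879 lower at stage 15. The odds ratio between the stages turned to 1.62 at 4-fold (Fisher's exact test, p = 0.309), on neither side past the threshold; the cause was not tested. Lists mostly higher at stage 15 dropped from 4 to 1 at 4-fold, because 3 of them had fewer than 5 listed members there. The Nodal list had 3 and the BMP list 2, all higher, and the FGF and ERK list had 0. They numbered 5 at an adjusted p under 0.01 and 5 with the genes of lowest mean count left out, where the p53 list also passed (exact binomial test, adjusted p = 0.0246 and 0.0156), as it did above the median mean count (0.0173). The anterior neural and eye list moved away from the threshold in these settings (0.214, 0.256 and 0.354). Against the 39.8% of higher genes among those with a symbol, 5 lists mostly higher and 1 mostly lower passed (exact binomial tests, adjusted p = 0.0214 for the p53, 0.0141 for the muscle and 0.110 for the anterior neural list). Bins at an adjusted p under 0.01 numbered 127 at stage 10 and 893 at stage 15, and 101 genes then had both a bin and a change in level at stage 15. With 1 bin per gene, 71 bins were shared by the stages. Leaving out each count column in turn, between 226 and 228 bins at stage 10 and between 1350 and 1378 at stage 15 had a raw mean at least 2-fold higher, against 227 and 1380 with all columns.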

Other observations

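All gene groups here were put together after the data were seen, and the choice of members may have followed the listed genes. Of the sarcomere group 29 of 45 members were listed at stage 15, and of the synaptic group 29 of 38. Of the muscle and somite list fixed beforehand, 16 of 50 were listed. The tests describe these lists and give no independent support. Genes of the germline were among those that rose at stage 15. All 9 listed genes of the piRNA pathway, which silences transposons in germ cells, were higher (exact binomial test, Benjamini-Hochberg adjusted p over 6 groups = 0.00231). In the authors' deposited table they included henmt1 (log2 fold change 2.92, SE 0.443), gpat2 (2.68, SE 0.404), tdrd12 (1.81, SE 0.405), mov10l1 (1.69, SE 0.310) and piwil3 (1.67, SE 0.412). All 5 listed genes of meiotic chromosomes were higher (adjusted p = 0.0223), led by the cohesin subunit gene smc1b (3.73, SE 0.843) in the authors' deposited table. Photoreceptor genes also rose, well before photoreceptors form: 11 of 12 listed members were higher (adjusted p = 0.00357), among them prph2 (3.76, SE 0.853) and grk7 (3.58, SE 0.746), with nrl lower (-3.68, SE 1.2), in the authors' deposited table. Some of these rest on few reads, as the mean normalised count was 4.45 for nrl and 8.34 for prph2 against 82.9 for grk7 in the authors' deposited table. Of the pigment genes 5 of 6 were higher, which did not pass the test (adjusted p = 0.0972), with gpnmb, slc45a2 (1.99, SE 0.560) and tyrp1 (1.70, SE 0.260) higher and oca2 lower (-1.32, SE 0.450) in the authors' deposited table.

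Genes of the contractile apparatus and of synapses fell at stage 15. Of 29 listed genes of the sarcomere and of excitation-contraction coupling, 28 were lower (adjusted p = 8.23e-06), including pdlim3 (-4.43, SE 0.561), pgam2 (-4.35, SE 0.920), myh1 (-4.27, SE 0.841) and the acetylcholine receptor organiser musk (-3.13, SE 0.522), with actn2 higher (1.91, SE 0.808), in the authors' deposited table. Of 29 listed genes of synaptic vesicles and neuronal channels, 24 were lower (adjusted p = 0.00357), including the glutamate receptor gene gria1 (-5.63, SE 0.771), the dopamine beta-hydroxylase gene dbh (-3.49, SE 0.835) and the synaptophysin gene syp (-2.66, SE 0.522) in the authors' deposited table. At stage 10 the junctophilin gene jph1 and the piRNA pathway gene mov10l1 (0.73, SE 0.230) were the only listed members of these 6 groups, and both were higher in the authors' deposited table. Against the 39.8% of higher genes among those with a symbol, all 6 groups passed (exact binomial tests, largest adjusted p = 0.0400, for pigment genes).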
